A study of Mus musculus with 12 samples.

How the data were processed

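Total RNA was isolated from kidneys with TRIzol, and mRNA libraries were made from 2 ug of it with a BGI kit, per the labels. The 12 libraries form 4 groups of 3: C57BL/6 at 8 weeks, C57BL/6 at 17 weeks, MRL/lpr at 8 weeks and MRL/lpr at 17 weeks. The expression table's columns were read by strain prefix, age and replicate number, with LN taken as MRL/lpr, C as C57BL/6 and W as weeks of age. The labels do not say whether the replicates of a group are separate animals, so each p value speaks of the spread between these libraries.

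The authors aligned the reads with Bowtie2 and estimated expression with RSEM 1.3.1 against GRCm38.p6, per the labels, which also name DESeq2 1.34.0. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), rounded to 2 decimals, for 72806 RefSeq mRNAs, of which 31263 are curated NM and 41543 predicted XM records. No unit is written in its header. FPKM was checked from the values, over mRNAs of known length. The value times the length in kilobases, scaled to all mRNAs, came to between 992127 and 1008827 per library. For FPKM the total of this product is the same in every library by construction. The columns add up to between 510180 and 532734. Read depths were estimated from the steps between low values. At the depth that fitted each library best, between 17300000 and 18700000 fragments, 57.4% to 65.4% of low values lay within 0.1 of a whole read, against 20% by chance. Since the rest did not, read counts were not recovered and no counting error is given.

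FPKM were summed over the mRNAs of each of 19034 gene identifiers, of which 18886 matched a gene symbol and 148 did not. A gene was tested when it reached 1 FPKM in at least 3 libraries, which left 12931 genes. Since the values are not counts, the design's choice for such values was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per group, a mean-variance trend and robust moderation. The comparisons were MRL/lpr against C57BL/6 at 8 weeks, at 17 weeks and averaged over both ages, 17 against 8 weeks in each strain, and the interaction of strain and age. P values were adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05, and all tests were two-sided. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

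The comparisons, the rule for naming genes, 47 gene lists and most alternatives were set before the data were examined. Single genes named are Fas, Nnt, Xist and the Y-linked genes, and up to 4 members of each list with a member past the threshold. Added to these are, per comparison, the 6 higher and 6 lower genes with the largest log2 differences among those past the threshold that reach 1 FPKM in the higher group and whose groups do not overlap. Predicted and ribosomal protein genes were left out, and some genes that meet the rule are not reported here. The interaction and the averaged difference were exempt from the condition of no overlap. Of the lists, 42 had at least 3 tested members. They hold 928 members (880 distinct genes), of which 893 were found and 746 tested. Lists were tested with camera from limma at a preset correlation between genes of 0.01, and again with the correlation estimated and with fry.

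Alternatives were 3 other scalings, other pseudocounts and filters, library weights, only the groups compared, only NM mRNAs, a minimum fold, the replicate number as a term, and leaving out each library in turn. Replicate numbers were checked for pairing between groups: 3 of 18 same-numbered pairs correlated above 0.1, with a median of -0.021 against 0.028 for other pairs, so the numbers were not used to pair samples. On simulated data with known changes, 67.2% of 1.5-fold, 83.6% of 2-fold and 89.4% of 4-fold changes were recovered in the 17-week strain comparison, with 3% false calls, and 29.9%, 62.7% and 75.8% in the interaction, with 1.8% false calls. Of 100 random lists, 2 and 5 had p under 0.05. The simulated noise was independent between genes and held no library that stands apart. These rates therefore need not hold for the real libraries, and least for lists of genes that vary together. No library or column was left out of the fit to all 12 libraries.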

Results

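RNA from the kidneys of MRL/lpr mice and of C57BL/6 mice was sequenced at 8 and 17 weeks of age. MRL/lpr mice carry the lpr mutation of Fas and develop a lupus-like autoimmune disease with kidney inflammation as they age, and C57BL/6 mice served as the controls. The series holds no MRL mice without lpr. A strain difference may therefore come from lpr, from the disease or from the rest of the strain background, which the design cannot tell apart. A difference between the ages may also come from the time of day of collection, which the labels do not give. The 4 groups held 3 libraries each, 12 in all, and the labels do not say whether the libraries of a group came from separate animals. Expression is given as FPKM summed over the mRNAs of each gene. The FPKM of a library added up to between 510180 and 532734, and between 12079 and 13011 genes reached 1 FPKM. Read counts are not known, so no counting intervals or detection limits are given. Levels are means ± SD of 3 libraries, log2 differences are given ± SE from a fit to all 12 libraries, and adjusted p values come from limma. Gene positions refer to GRCm38.p6, the mouse reference genome, which comes from C57BL/6J.

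Fas (gene ID 14102, chromosome 19, 34290647 to 34327775) encodes the death receptor that the lpr mutation disrupts, and Nnt (gene ID 18115, chromosome 13, 119335527 to 119409257) encodes a mitochondrial transhydrogenase that is deleted in part in C57BL/6J mice. Nnt stood at 49.8 ± 2.66 FPKM in C57BL/6 and 108 ± 13.0 in MRL/lpr kidneys at 8 weeks, a log2 difference of 1.10 ± 0.14 (adjusted p = 0.000373). At 17 weeks Nnt differed by 1.16 ± 0.14 on the log2 scale (adjusted p = 0.000291). Fas averaged 7.44 ± 0.217 FPKM in C57BL/6 and 5.40 ± 0.663 in MRL/lpr kidneys at 8 weeks, and the difference of -0.40 ± 0.16 did not pass the threshold (adjusted p = 0.145). Without C57BL/6 17 weeks replicate 2 the Fas difference at 8 weeks passed (adjusted p = 0.0129), and over all settings tried its adjusted p ranged from 0.00978 to 0.362. At 17 weeks Fas averaged 7.35 ± 2.26 and 6.80 ± 0.962 FPKM (adjusted p = 0.815). The most abundant Fas mRNA lay between 5.19 and 8.6 FPKM in the 6 C57BL/6 libraries and between 3.77 and 5.33 in the 6 MRL/lpr libraries. Trim12a, which is known to differ between mouse strains, stood at 6.37 ± 0.554 FPKM in C57BL/6 and 0.0467 ± 0.0404 in MRL/lpr kidneys at 8 weeks (log2 -2.82 ± 0.23, adjusted p = 1.71e-05). Of the Y-linked genes, Ddx3y and Kdm5d stayed at or below 0.02 FPKM in all 12 libraries, Uty lay between 0.11 and 0.24, and Eif2s3y between 0.27 and 0.58. The labels give no sex, and Xist, which is not an mRNA, has no value in the table.

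The strains separated along the first principal component, which held 47.4% of the variance. C57BL/6 libraries lay between 13.23 and 29.47 on it and MRL/lpr libraries between -30.05 and -18.14. The second component held 29.5% and set C57BL/6 17 weeks replicate 2, at -55.29, apart from the other 11 libraries, which lay between -11.85 and 26.84. In that library 886 genes were more than 2-fold above the mean of its 2 partners and 62 more than 2-fold below it. Macrophage and monocyte markers stood a median of 2.52 above the partners on the log2 scale, neutrophil markers 2.05, tubular injury markers 1.91 and T cell markers 1.23, and proximal tubule markers -0.53. Lcn2, a secreted marker of injured tubules, was at 180.4 FPKM against 1.83 and 3.04 in the partners, and Havcr1 was at 37.4 against 0.33 and 0.39. MRL/lpr 8 weeks replicate 3 stood apart less, with 139 genes more than 2-fold above and 11 below its partners. Its mean log2 level of MHC class II genes was 5.85, against 4.38 and 4.24 in the partners, and that of T cell markers 1.54, against 1.07 and 0.99.

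**Figure D1:**
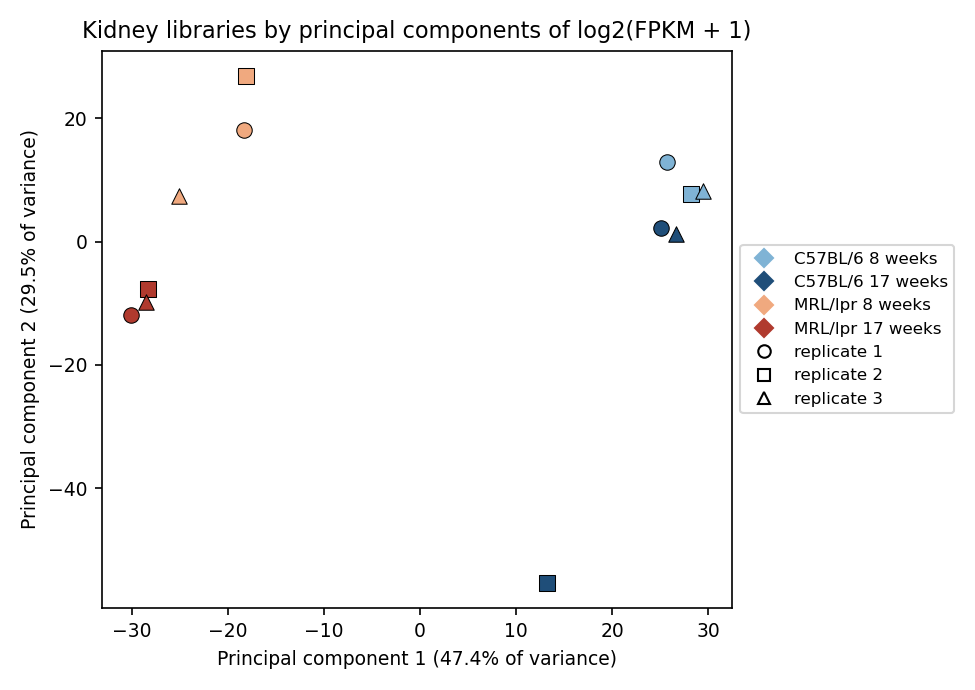
Principal components 1 and 2 of log2(FPKM + 1) over the tested genes, with 1 point per library coloured by strain and age. The strains separate along component 1, and C57BL/6 17 weeks replicate 2 lies at -55.29 on component 2.

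**Figure D2:**
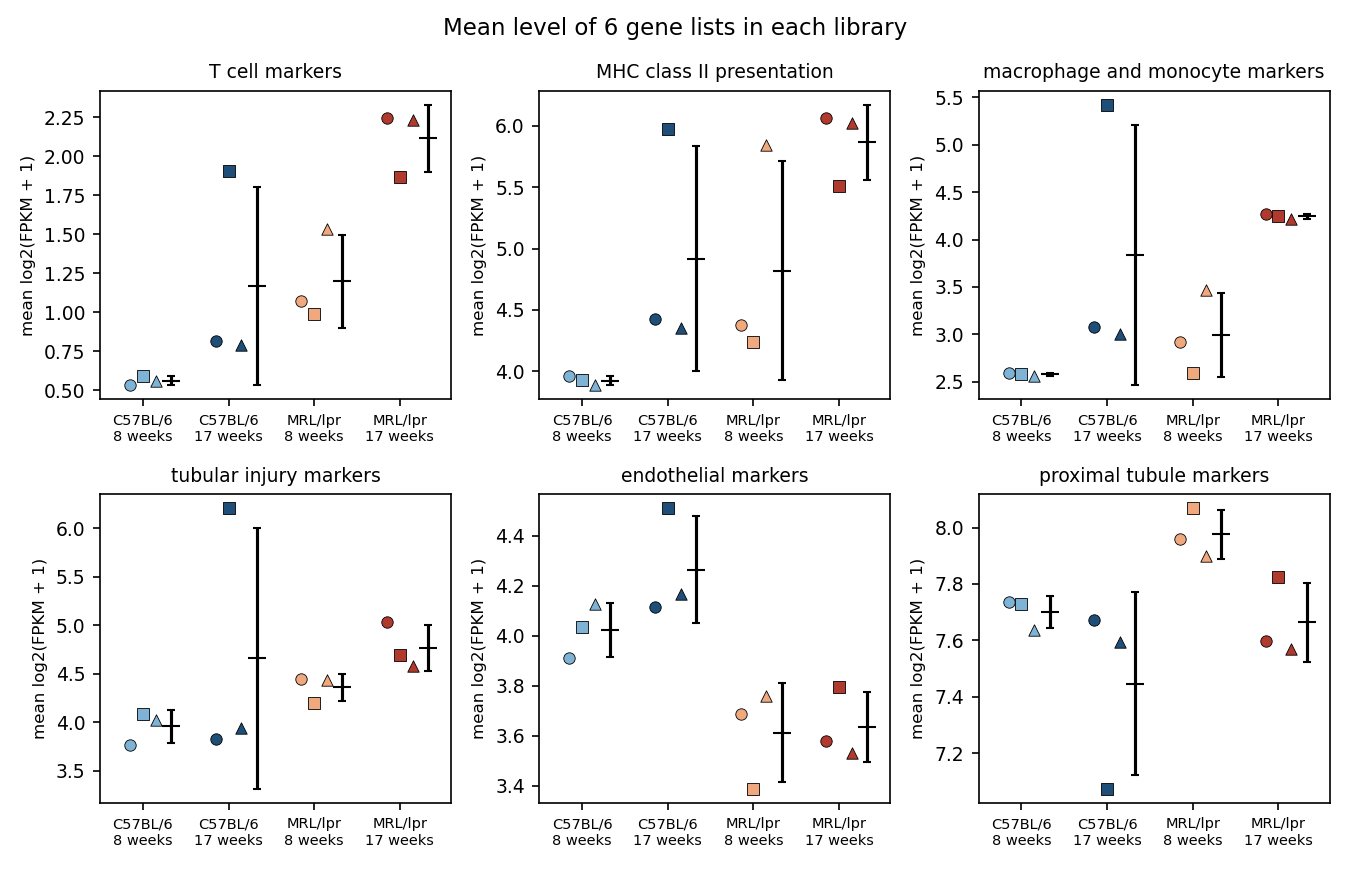
Mean log2(FPKM + 1) of 6 gene lists in each of the 12 libraries, with 1 point per library and a bar for the mean ± SD of each group of 3. C57BL/6 17 weeks replicate 2 has a macrophage and monocyte mean of 5.42, against 3.08 and 3.01 in its partners.

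The comparison of MRL/lpr with C57BL/6 kidneys at 8 weeks asks how the lupus-prone kidney differs early in life. Havcr1 (gene ID 171283, chromosome 11, 46739822 to 46779578) encodes the injury marker KIM-1 of the proximal tubule. It stood at 125 ± 27.5 FPKM in MRL/lpr and 0.417 ± 0.0503 in C57BL/6 kidneys, a log2 difference of 6.46 ± 1.07 (adjusted p = 0.00262). The tubular injury list, of which Havcr1 is a member, was not called at 8 weeks (camera adjusted p = 0.479). Its members Lcn2 (-0.396 ± 1.254) and Spp1 (0.295 ± 0.388) did not pass the threshold (adjusted p = 0.884 and 0.693 by limma). Angptl7 (gene ID 654812, chromosome 4, 148495181 to 148500462), a secreted angiopoietin-like protein, stood at 179 ± 51.6 against 1.74 ± 0.148 FPKM (log2 6.00 ± 0.20, adjusted p = 1.75e-08). Serpina6, the corticosteroid-binding globulin, was higher by 4.25 ± 0.47. Cd8a (gene ID 12525, chromosome 6, 71373427 to 71379171), the coreceptor of cytotoxic T cells, lay between 12.4 and 15.9 FPKM in all 6 MRL/lpr libraries of both ages and at or below 1.65 in the C57BL/6 libraries (log2 3.11 ± 0.14 at 8 weeks, adjusted p = 1.55e-07). It is also on the list of genes with known strain variants, and between the ages in MRL/lpr kidneys it differed by 0.02 ± 0.14 (adjusted p = 0.944). Ttr (gene ID 22139, chromosome 18, 20664209 to 20674326), the carrier of thyroxine and retinol-binding protein, was lower in MRL/lpr kidneys at 0.923 ± 0.180 against 48.4 ± 4.03 FPKM (log2 -4.68 ± 0.11, adjusted p = 1.27e-09; log2 -2.02 over its curated NM mRNAs alone). The securin gene Pttg1 (gene ID 30939, chromosome 11, 43420244 to 43427463) differed by -3.37 ± 0.14. The actin-capping gene Capg (gene ID 12332, chromosome 6, 72538282 to 72562983) differed by -4.05 ± 0.18 over all its mRNAs, and by -0.88 (adjusted p = 0.338) over its curated NM mRNAs alone.

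Of the 6 higher and 6 lower genes singled out by size at 8 weeks, 6 have a near-identical copy. Eno1b (gene ID 433182, chromosome 18, 48045335 to 48048379) stood at 309 ± 5.05 FPKM in MRL/lpr and 0.740 ± 0.288 in C57BL/6 kidneys (log2 7.49 ± 0.18, adjusted p = 1.66e-09), while the summed FPKM of Eno1 and Eno1b differed by 0.05 ± 0.07. Hmga1b was at 17.9 ± 0.604 FPKM in MRL/lpr kidneys and listed at 0 in all C57BL/6 libraries, and its sum with Hmga1 differed by 0.44 ± 0.03. Rnaset2b was at 101 ± 7.19 FPKM in C57BL/6 kidneys and listed at 0 in all MRL/lpr libraries, and its sum with Rnaset2a differed by 0.22 ± 0.04. Hba-a2 differed by -3.89 ± 0.87 and its sum with Hba-a1 by 0.88 ± 0.73, and the Hba-a2 call was lost without C57BL/6 8 weeks replicate 2 or 3 or MRL/lpr 8 weeks replicate 2 (adjusted p up to 0.0603). Gsta1 was higher by 5.13 ± 0.35 while Gsta2 differed by -1.77 ± 0.26 and their sum by -1.41 ± 0.30. Serpina1d differed by -5.60 ± 0.26, and its sum with the other Serpina1 genes by -3.16 ± 0.24.

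At 8 weeks 4 immune lists were called, those of T cell, MHC class II, MHC class I and NK genes, all higher in MRL/lpr kidneys. Not called were macrophage (median 0.39, adjusted p = 0.108), chemokine (0.50, 0.222), interferon-stimulated (-0.01, 0.690) and B cell genes (0.06, 0.846), nor the plasma cell, dendritic, neutrophil, cytokine, complement, nucleic acid sensing and inflammasome lists (adjusted p of 0.279 or more). The T cell list had a median log2 difference of 0.49, adjusted p = 0.000877 (camera), with 2 of 19 members higher and 17 not past the threshold (2 higher adjusted over the list alone), among them Cd8a. With an estimated correlation the 12 lists called at 8 weeks, those that follow included, lost their calls (adjusted p = 0.160 for male-biased, 0.231 for hepatocyte and 0.936 for the other 10). MHC class II genes had a median of 0.71, adjusted p = 0.0140, with 1 of 12 higher (1 adjusted over the list alone). MHC class I genes had 0.59, adjusted p = 0.0399, with 0 of 18 higher and 1 lower by limma, where 3319 of all genes had an unadjusted p under 0.05 (0 adjusted over the list alone). NK and cytotoxic cell genes had 0.58, adjusted p = 0.0448, with 1 of 7 higher (1 adjusted over the list alone). Endothelial genes leaned the other way, with a median of -0.39, adjusted p = 0.000136 and 3 of 18 lower (8 adjusted over the list alone), such as Robo4 (log2 -0.73 ± 0.15). Hepatocyte markers had a median of -1.51, adjusted p = 0.000127, with 6 of 9 lower and 1 higher (6 and 1 adjusted over the list alone), such as Apoa2 (-3.20 ± 0.27) and Ttr. Male-biased kidney genes had a median of 0.55, adjusted p = 0.000136, with 4 of 13 higher (6 adjusted over the list alone), including Cyp4b1 (2.41 ± 0.26), Slc7a13 (1.92 ± 0.19) and Cyp4a12a (1.43 ± 0.25). Kap, the most abundant member of that list, differed by -0.41 ± 0.37 (adjusted p = 0.552 by limma). Cyp4b1 and Slc7a13 were also the 2 of 29 proximal tubule genes that were higher (2 adjusted over the list alone). The proximal tubule list had a median of 0.16 (camera adjusted p = 0.0147). Among collecting duct genes (median -0.23, adjusted p = 0.0140) 4 of 19 were lower (5 adjusted over the list alone), such as the proton pump subunit Atp6v1g3 (-0.66 ± 0.11). The endoplasmic reticulum stress list had a median of 0.27, adjusted p = 0.00120 with 3 of 20 higher (7 adjusted over the list alone). The cell cycle list had 0.27, adjusted p = 0.0123 with 2 of 26 higher (2 adjusted over the list alone), such as Stmn1 (1.22 ± 0.14). Nuclear oxidative phosphorylation had -0.12, adjusted p = 0.0421 with 2 of 34 lower (0 adjusted over the list alone by limma).

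Outside the lists called at 8 weeks, renin (Ren1, gene ID 19701, chromosome 1, 133350674 to 133360320) stood at 303 ± 42.0 FPKM in MRL/lpr and 118 ± 3.29 in C57BL/6 kidneys (log2 1.3 ± 0.15, adjusted p = 0.000163). Its substrate Agt was higher by 0.62 ± 0.13. Col5a2 (-2.18 ± 0.13), the pericyte gene Rgs5 (-1.16 ± 0.20), the cholesterol synthesis genes Sqle (-1.21 ± 0.18) and Sc5d (-1.14 ± 0.10), Pdk4 (-1.60 ± 0.24), Cxcl14 (-1.69 ± 0.20) and the ferritin heavy chain Fth1 (-0.62 ± 0.065) were lower in MRL/lpr kidneys in all fits with 1 library left out. The aminoacylase gene Acy1 (1.11 ± 0.16) was higher in all of them. In all, 760 of 12931 genes were higher and 900 lower at an adjusted p of 0.05, 168 and 160 of them by at least 2-fold. The total of 1660 became 1078 without C57BL/6 8 weeks replicate 3 and 2986 without C57BL/6 17 weeks replicate 2, with all 1660 among the latter. Of the 43 genes singled out at 8 weeks, 33 kept their calls whichever library was left out, and 5 were lost over NM mRNAs alone (adjusted p up to 0.575). Lists that kept theirs were T cell, endothelial, hepatocyte, male-biased and endoplasmic reticulum stress genes, 5 of 12. With C57BL/6 17 weeks replicate 2 left out, which is not in this comparison but adds to the shared spread, 14 lists were called. Members past the threshold were then 7 of 19 T cell genes and 6 of 27 macrophage genes, all higher, and 9 of 18 endothelial genes, lower (7, 4 and 13 adjusted over the list alone; adjusted p = 0.731 with an estimated correlation). Without MRL/lpr 8 weeks replicate 3 the calls of MHC class I (adjusted p = 0.692), MHC class II (0.207), NK (0.177), cell cycle (0.0935), collecting duct (0.207) and oxidative phosphorylation genes (0.180) were lost. MHC class I and NK calls were also lost without C57BL/6 8 weeks replicate 2 or 3 (up to 0.0667), and the NK call without MRL/lpr 17 weeks replicate 1 (0.0549). Further calls lost were oxidative phosphorylation without C57BL/6 8 weeks replicate 1 or 2 (up to 0.176) and proximal tubule genes without MRL/lpr 8 weeks replicate 2 (0.0699). With median-of-ratios scaling the MHC class I, NK and oxidative phosphorylation calls were lost (adjusted p = 0.0511, 0.0618 and 0.128).

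At 17 weeks, an age at which MRL/lpr mice are known to have overt disease, Angptl7 stood at 263 ± 46.1 FPKM in MRL/lpr and 2.33 ± 0.561 in C57BL/6 kidneys (log2 6.31 ± 0.20, adjusted p = 1.19e-08). Chil1 (gene ID 12654, chromosome 1, 134182156 to 134190031), a secreted chitinase-like protein, stood at 16.6 ± 6.36 against 0.180 ± 0.121 FPKM (log2 3.82 ± 0.28, adjusted p = 7.99e-06). The growth factor gene Igf2 (gene ID 16002, chromosome 7, 142650768 to 142666816) was lower in MRL/lpr kidneys at 3.77 ± 1.14 against 81.2 ± 10.8 FPKM (log2 -4.13 ± 0.35, adjusted p = 2.71e-05). Ttr differed by -4.68 ± 0.11 and H2bc1, a testis-type histone gene, was at 22.8 ± 6.30 FPKM in MRL/lpr kidneys and listed at 0 in C57BL/6. Capg differed by -3.47 ± 0.18, and by -1.58 over its NM mRNAs alone (adjusted p = 0.0706). The genes with near-identical copies Eno1b (7.33 ± 0.18), Gsta1 (4.2 ± 0.35), Serpina1d (-4.74 ± 0.26) and Hba-a2 (-4.39 ± 0.87) differed in the same direction as at 8 weeks, and Hmga1b was again listed at 0 in C57BL/6 and Rnaset2b in MRL/lpr. Sums over copies differed by 0.16 ± 0.04 for Eno1, -0.69 ± 0.28 for Gsta1 and Gsta2, -1.26 ± 0.42 for Serpina1, -0.23 ± 0.69 for Hba-a, 0.43 ± 0.33 for Hmga1 and 0.36 ± 0.04 for Rnaset2. Havcr1 was higher by 4.28 ± 1.07 (adjusted p = 0.0231), a value that became 5.88 without C57BL/6 17 weeks replicate 2. The call was lost without C57BL/6 17 weeks replicate 1 or 3 or MRL/lpr 17 weeks replicate 1 or 2 (adjusted p up to 0.0846). With all 12 libraries the tubular injury list was not called at 17 weeks (camera adjusted p = 0.898).

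At 17 weeks the same 4 immune lists were called. Not called were B cell (median 0.61, adjusted p = 0.195), chemokine (0.20, 0.268), interferon-stimulated (0.12, 0.291) and macrophage genes (0.27, 0.333), nor the plasma cell, dendritic, neutrophil, cytokine, complement, nucleic acid sensing and inflammasome lists (adjusted p of 0.380 or more). The T cell list had a median log2 difference of 0.93, adjusted p = 9.45e-07 (camera), with 7 of 19 members higher and 12 not past the threshold (12 higher adjusted over the list alone). With an estimated correlation the 9 lists called at 17 weeks lost their calls (adjusted p = 0.201 for hepatocyte, 0.503 for male-biased and 0.985 for the other 7). Cd8a was higher by 2.88 ± 0.14, Cxcl9, a T cell attractant that interferon gamma induces, by 2.23 ± 0.29, and the interferon-induced GTPase gene Gbp2 by 2.78 ± 0.57, in all fits with 1 library left out. Cd3d was higher by 1.26 ± 0.33 and the MHC class II loading gene H2-DMb2 by 3.14 ± 0.74. Both calls were lost without C57BL/6 17 weeks replicate 1 or 3 or MRL/lpr 17 weeks replicate 1 or 3 (adjusted p up to 0.101 and 0.0646). H2-DMb2 already differed by 3.08 ± 0.74 at 8 weeks (adjusted p = 0.0203 by limma). Reads of both strains were aligned to the C57BL/6J reference, and what this adds to the differences of MHC genes was not tested. MHC class I genes had a median of 0.93, adjusted p = 0.00349, with 2 of 18 higher (2 adjusted over the list alone). MHC class II genes had 0.68, adjusted p = 0.0231, with 2 of 12 higher (2 adjusted over the list alone). NK and cytotoxic cell genes had 0.96, adjusted p = 0.0258, with 3 of 7 higher (5 adjusted over the list alone). Endothelial genes had a median of -0.66, adjusted p = 3.43e-08, with 13 of 18 lower and 5 not past the threshold (15 lower adjusted over the list alone). Examples were Robo4 (-1.28 ± 0.15), Plvap (-0.70 ± 0.17) and the cadherin gene Cdh5 (-0.79 ± 0.20). The Plvap and Cdh5 calls were lost without MRL/lpr 17 weeks replicate 1 or 3, and that of Plvap also without C57BL/6 17 weeks replicate 3 (adjusted p up to 0.0691 and 0.0853). Hepatocyte markers had a median of -1.90, adjusted p = 8.94e-07, with 6 of 9 lower (8 adjusted over the list alone), including Fgb (-2.87 ± 0.19) and Apoa2 (-3.08 ± 0.27). The hepatocyte gene Alb was at 60.4 FPKM in C57BL/6 17 weeks replicate 3 against at most 11.8 in the other 11 libraries. Male-biased genes (0.29, adjusted p = 0.0158) had 6 of 13 higher (6 adjusted over the list alone), such as Slc7a13 (1.56 ± 0.19). Amino acid metabolism genes (0.23, adjusted p = 0.00242) had 4 of 28 higher (4 adjusted over the list alone), such as Acy1 (1.82 ± 0.16) and Acy3 (1.04 ± 0.11). Cell cycle genes (0.29, adjusted p = 0.0269) had 1 of 26 higher (1 adjusted over the list alone), which was Stmn1 (1.2 ± 0.14).

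Complement factor I (Cfi, -2.0 ± 0.36), Cxcl14 (-1.73 ± 0.20), Col5a2 (-1.80 ± 0.13), Trim12a (-3.11 ± 0.23) and Fth1 (-0.38 ± 0.065) were lower in MRL/lpr kidneys at 17 weeks in all fits with 1 library left out. Ren1 (0.86 ± 0.15) was higher in all of them. Of 12931 genes, 993 were higher and 962 lower, 219 and 131 of them by at least 2-fold. The total of 1955 became 3521 without C57BL/6 17 weeks replicate 2 (2281 higher, 1240 lower, 1811 of them shared), 1279 without MRL/lpr 17 weeks replicate 1 and 1291 without replicate 2 of that group. Of the 44 genes singled out at 17 weeks, 29 kept their calls whichever library was left out, and 6 were lost over NM mRNAs alone (adjusted p up to 0.0838). Lists that kept theirs were MHC class I, T cell, endothelial and hepatocyte genes, 4 of 9. Without C57BL/6 17 weeks replicate 2 the amino acid call (median 0.11, adjusted p = 0.712) and the male-biased call (0.42, 0.0708) were lost and the number of lists called rose from 9 to 15. The macrophage and monocyte list then had a median of 1.12, with 20 of 27 members higher, and the tubular injury list 0.61, with 8 of 18 higher (21 and 11 adjusted over the list alone). With an estimated correlation both had an adjusted p of 0.610. In the same fit 18 of 19 T cell, 12 of 18 MHC class I, 7 of 12 MHC class II, 5 of 7 NK and 18 of 26 cell cycle genes were higher (19, 14, 10, 6 and 22 adjusted over the list alone). The medians of the MHC lists became 1.29 and 1.31 and that of the cell cycle list 0.55 (adjusted p of up to 0.674 for these 5 with an estimated correlation). Also called in that fit were interferon-stimulated (0.61, adjusted p = 0.00236, 15 of 43 higher and 1 lower), chemokine (0.88, 0.000110, 17 of 25 and 1), B cell (0.88, 0.0414, 6 of 9) and nucleic acid sensing genes (0.48, 0.00634, 11 of 17 and 1). Adjusted over the list alone 18, 18, 6 and 14 of them were higher. Endoplasmic reticulum stress genes (0.26, 0.0380) had 6 of 20 higher and oxidative phosphorylation genes (-0.09, 0.00911) 7 of 34 lower and 1 higher, the same adjusted over the list alone. These 6 had adjusted p values of up to 0.738 with an estimated correlation. The MHC class II call was lost without C57BL/6 17 weeks replicate 1 or 3 or MRL/lpr 17 weeks replicate 1 (up to 0.0909). The NK call was lost without C57BL/6 17 weeks replicate 3 or MRL/lpr 17 weeks replicate 1 (up to 0.0709), and the cell cycle call without C57BL/6 17 weeks replicate 1 or 3 or MRL/lpr 17 weeks replicate 1 (up to 0.299).

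**Figure D3:**
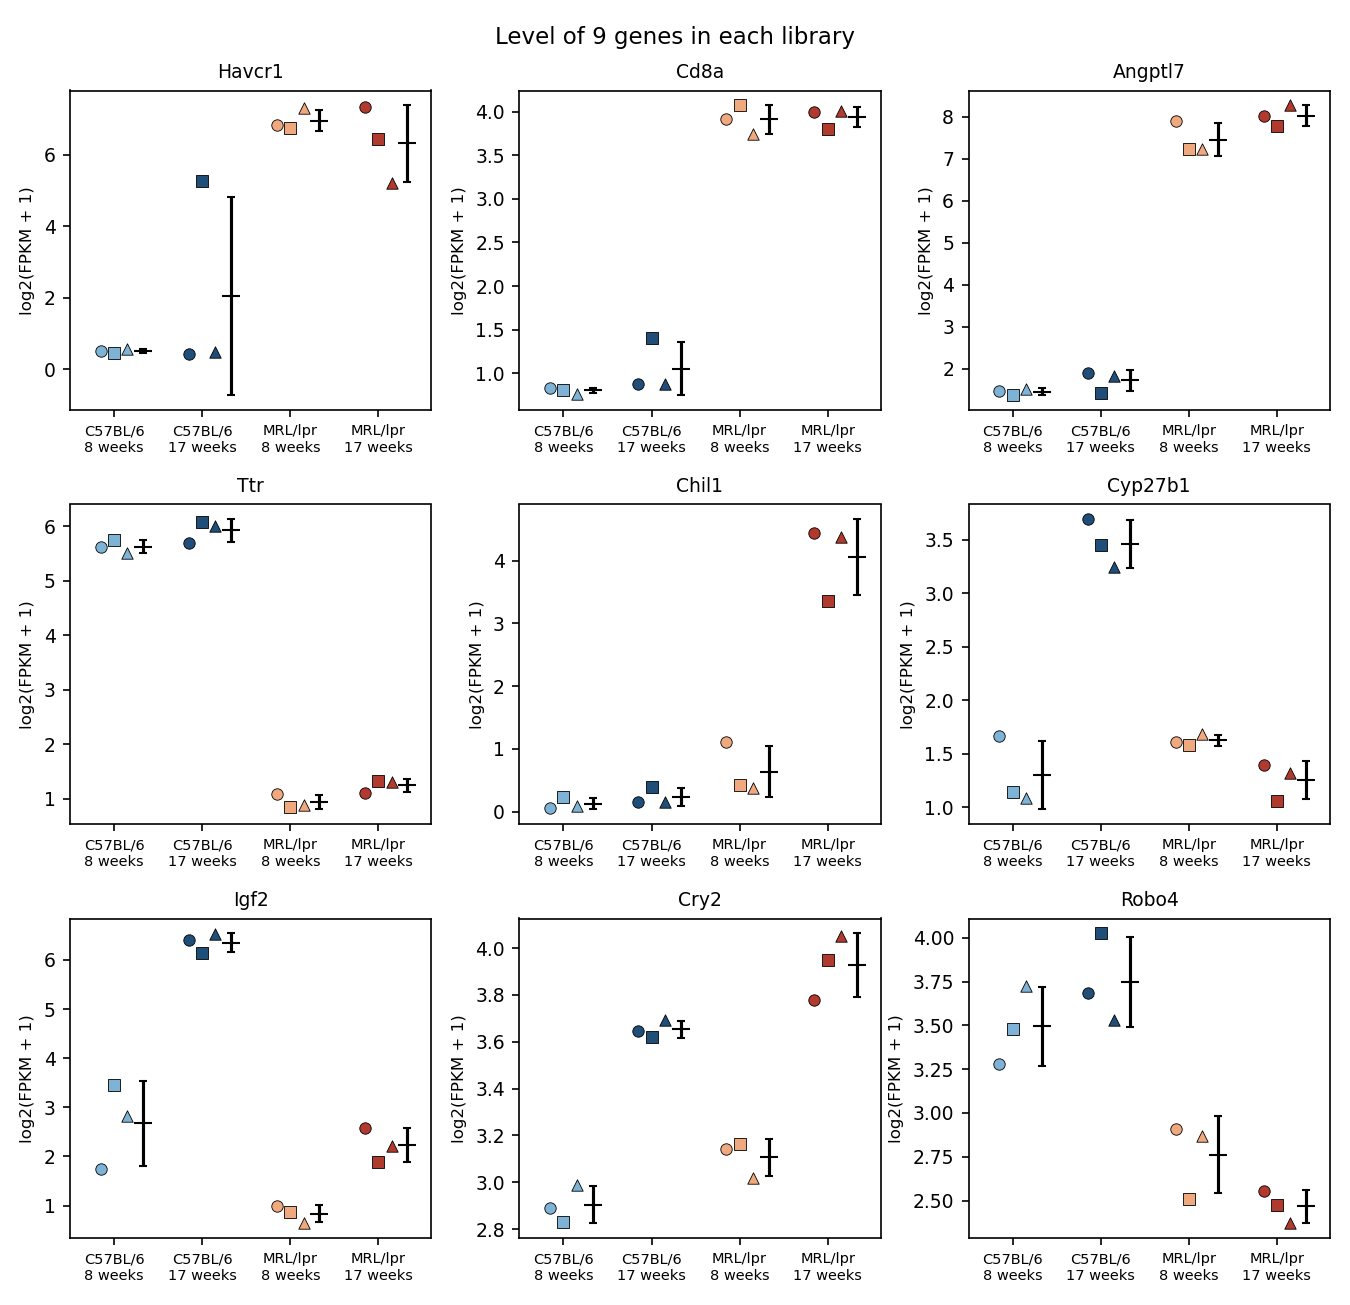
Expression as log2(FPKM + 1) of Havcr1, Cd8a, Angptl7, Ttr, Chil1, Cyp27b1, Igf2, Cry2 and Robo4, with 1 point per library and a bar for the mean ± SD of each group of 3. Cd8a and Angptl7 are higher and Ttr lower in all 6 MRL/lpr libraries, and Chil1 is highest in the MRL/lpr 17 weeks libraries.

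The strain difference averaged over both ages asks what sets MRL/lpr kidneys apart at either age. Angptl7 (6.16 ± 0.14), Eno1b (7.41 ± 0.13) and Havcr1 (5.37 ± 0.76) were higher and Ttr (-4.68 ± 0.081) lower on the log2 scale, and H2bc1 was listed at 0 in C57BL/6 and Rnaset2b in MRL/lpr. These 6 calls held whichever library was left out. Eno1b and Rnaset2b are the near-identical copies described at 8 weeks. Without C57BL/6 17 weeks replicate 2 the averaged Havcr1 difference was 6.17. With all 12 libraries the tubular injury list was not called on average (camera adjusted p = 0.836). T cell genes had a median of 0.64, adjusted p = 4.61e-06 with 11 of 19 higher (13 adjusted over the list alone), and endothelial genes -0.52, adjusted p = 2.14e-07 with 15 of 18 lower (17 adjusted over the list alone). With an estimated correlation the 11 lists called here lost their calls (adjusted p = 0.164 for hepatocyte and male-biased genes and 0.963 for the other 9). Hepatocyte genes had -2.04, adjusted p = 8.07e-06 with 7 of 9 lower and 1 higher (8 and 1 adjusted over the list alone). Male-biased genes had 0.39, adjusted p = 0.000627 with 6 of 13 higher (8 adjusted over the list alone). MHC class I genes had 0.73, adjusted p = 0.00351 with 6 of 18 higher and 1 lower (11 and 1 adjusted over the list alone) and MHC class II genes 0.74, adjusted p = 0.00441 with 4 of 12 higher (5 adjusted over the list alone). The NK (0.77, adjusted p = 0.0142), cell cycle (0.30, adjusted p = 0.00441), endoplasmic reticulum stress (0.23, adjusted p = 0.00548), amino acid (0.19, adjusted p = 0.00351) and proximal tubule lists (0.09, adjusted p = 0.0118) were also called. The amino acid call was lost without C57BL/6 17 weeks replicate 2 (0.157) and the proximal tubule call without that library or MRL/lpr 17 weeks replicate 2 (up to 0.431). Called only without C57BL/6 17 weeks replicate 2 were macrophage (0.66, adjusted p = 1.33e-07), chemokine (0.62, 0.000885), tubular injury (0.34, 0.0159) and oxidative phosphorylation genes (-0.07, 0.00266). So were nucleic acid sensing genes (0.20, 0.0306). By limma 22 of 27 macrophage and 9 of 18 tubular injury genes were then higher. With an estimated correlation all these lists had an adjusted p of 0.630. In all, 1484 genes were higher and 1624 lower, and between 2442 and 4651 passed with 1 library left out. The comparisons at 8 and at 17 weeks share no library. In both, 487 genes were higher, against 58.4 expected of independent lists, and 543 lower, against 67, while 6 and 4 genes were called in opposite directions. Both comparisons used the same fitted spread of each gene, so the lists were not independent and the expected numbers are only a rough guide.

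Change with age in C57BL/6 kidneys shows how the control kidney differs between these ages. Igf2 rose from 6.16 ± 3.83 to 81.2 ± 10.8 FPKM (log2 3.67 ± 0.35, adjusted p = 0.00224). Cyp27b1 (gene ID 13115, chromosome 10, 127048246 to 127054884), whose enzyme makes active vitamin D, rose from 1.5 ± 0.579 to 10.1 ± 1.74 (log2 2.17 ± 0.16, adjusted p = 0.000814). The clock repressor gene Cry2 (gene ID 12953, chromosome 2, 92403646 to 92434085) rose by 0.75 ± 0.077, and by 1.08 with an adjusted p of 0.0827 over its NM mRNAs alone. The melanin-concentrating hormone receptor gene Mchr1 fell by 1.23 ± 0.13. These 4 calls held whichever library was left out. Tmprss6 (1.82 ± 0.24), Azgp1 (1.54 ± 0.32), Cyp4b1 (1.51 ± 0.26), Aldh1a1 (1.41 ± 0.20), Fgb (1.3 ± 0.19) and Cfb (0.40 ± 0.08) rose. Rnf24 (-2.57 ± 0.39), the steroid reductase genes Akr1c14 (-1.89 ± 0.35) and Akr1d1 (-1.23 ± 0.19), H4c8 (-1.18 ± 0.18), Pllp (-1.12 ± 0.16), Odc1 (-0.57 ± 0.089), Col4a3 (-0.50 ± 0.088) and the organic acid transporter genes Slc22a12 (-0.68 ± 0.11) and Slc22a6 (-0.76 ± 0.16) fell. Each of these 15 calls was lost in at least 1 fit with a library left out, which leaves a group of 2. Leaving out C57BL/6 8 weeks replicate 1, 2 or 3 ended 15, 10 or 14 of them, and C57BL/6 17 weeks replicate 1, 2 or 3 ended 6, 2 or 11. The MRL/lpr 8 weeks libraries ended 4, 3 and 3 and the MRL/lpr 17 weeks libraries 1, 2 and 1, with adjusted p values of up to 0.166. Over NM mRNAs alone the calls of Akr1c14, Azgp1, Cfb and Slc22a6 were lost (up to 0.0764), and Akr1d1 was not tested.

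Immune and injury lists stood higher at 17 weeks in C57BL/6 kidneys in the fit to all 12 libraries, with few single genes past the threshold. The macrophage and monocyte list had a median log2 difference of 1.26, adjusted p = 1.94e-07 (camera) and the T cell list 0.64, adjusted p = 0.000105. By limma 0 of 27 and 0 of 19 members passed the threshold, also adjusted over the list alone, where 2527 of all genes had an unadjusted p under 0.05. With an estimated correlation the 21 lists called had adjusted p values between 0.701 and 0.710. Chemokine genes had a median of 0.82, adjusted p = 2.33e-05, with 0 of 25 past the threshold (2 adjusted over the list alone). Complement genes had 0.87, adjusted p = 0.000158, with 1 of 20 higher (4 adjusted over the list alone), which was Cfb. Hepatocyte genes had 0.83, adjusted p = 0.00104, with 2 of 9 higher (5 adjusted over the list alone), where C57BL/6 17 weeks replicate 3 held 60.4 FPKM of Alb. These 5 of the 21 lists called kept their calls whichever library was left out. Their medians without C57BL/6 17 weeks replicate 2 were 0.50 for macrophage, 0.27 for T cell, 0.28 for chemokine, 0.35 for complement and 1.05 for hepatocyte genes (adjusted p = 0.918 with an estimated correlation). The other 16 were lost without C57BL/6 17 weeks replicate 2, when 5 lists in all were called. Among them were the tubular injury list (0.61, adjusted p = 0.0214, and 0.971 without it), MHC class II (1.09, adjusted p = 0.00138, and 0.0564 without it) and interferon-stimulated genes (0.38, adjusted p = 0.0214, and 0.799 without it). Without that library the medians of these 3 were -0.04, 0.45 and -0.10. By limma 0 of their 18, 12 and 43 members passed the threshold, also adjusted over the lists alone. The proximal tubule list leaned lower (-0.31, adjusted p = 2.99e-05, and -0.09 with 0.506 without it), and in it 4 of 29 fell and 1 rose (6 and 1 adjusted over the list alone). The tubular injury and interferon lists were also lost without C57BL/6 8 weeks replicate 1 (0.0537 and 0.0690). In all, 80 of 12931 genes rose and 113 fell, 13 and 8 of them by at least 2-fold. The total of 193 became 92, 375 and 36 without C57BL/6 17 weeks replicates 1, 2 and 3, and 15, 32 and 21 without C57BL/6 8 weeks replicates 1, 2 and 3. It became 94 without MRL/lpr 17 weeks replicate 2 and 77, 105 and 108 without MRL/lpr 8 weeks replicates 1, 2 and 3, and it was 117 with median-of-ratios scaling.

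Change with age in MRL/lpr kidneys follows the strain into the age of disease. Chil1 rose from 0.597 ± 0.480 to 16.6 ± 6.36 FPKM (log2 3.42 ± 0.28, adjusted p = 0.000564) and the secreted phospholipase gene Pla2g2d from 0.270 ± 0.0964 to 5.31 ± 1.81 (log2 2.27 ± 0.25, adjusted p = 0.00283). The seminal vesicle secretory genes Svs4 and Svs5 reached 2.77 ± 1.3 and 2.84 ± 1.24 FPKM at 17 weeks and were listed at 0 in the 9 other libraries. Palld, an actin-bundling protein gene, fell from 36.04 ± 4.33 to 16.8 ± 2.22 FPKM (log2 -1.06 ± 0.10, adjusted p = 0.00154) and Banp by 1.11 ± 0.12. Cry2 rose by 0.82 ± 0.077, and by 0.43 with an adjusted p of 0.401 over its NM mRNAs alone. These 7 calls held whichever library was left out. The acute-phase gene Saa3 (2.20 ± 0.48), Wfdc17 (2.23 ± 0.40), Cxcl9 (1.65 ± 0.29), Cd3d (1.52 ± 0.33), Lag3 (1.19 ± 0.24), Cd79b (1.26 ± 0.25), Ccl3 (0.91 ± 0.20) and Cry1 (1.35 ± 0.29) also rose. Serpina6 (-2.50 ± 0.47), Hsd3b2 (-1.22 ± 0.27), Pllp (-0.97 ± 0.16), Ren1 (-0.88 ± 0.15), Slc22a12 (-0.68 ± 0.11), Gatm (-0.63 ± 0.13) and Odc1 (-0.44 ± 0.089) fell. Bcl6 fell by 1.59 ± 0.30, and by 0.92 with an adjusted p of 0.347 over its NM mRNAs alone. Calls of these 16 genes were lost with 1 library left out, 14 of them without each of the MRL/lpr 8 weeks replicates and 8, 11 and 15 without MRL/lpr 17 weeks replicates 1, 2 and 3. The losses were 5, 7 and 6 without C57BL/6 8 weeks replicates 1, 2 and 3, and 2 without C57BL/6 17 weeks replicate 3, with adjusted p values of up to 0.131. Over NM mRNAs alone the calls of Ccl3, Cd79b, Cry1, Gatm, Hsd3b2, Lag3 and Saa3 were lost as well (up to 0.0784), and Cd3d was not tested.

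In MRL/lpr kidneys 14 lists were called with age, 11 higher and 3 lower at 17 weeks. The NK (median 0.34, adjusted p = 0.0634), dendritic (0.28, 0.183), neutrophil (0.71, 0.515), inflammasome (0.40, 0.0832) and tubular injury lists (0.49, 0.566) were not called. Without MRL/lpr 8 weeks replicate 3 the NK and dendritic lists were called, and the NK list also without MRL/lpr 17 weeks replicate 2. Their adjusted p went down to 0.00369 and 0.001003 in these fits, in which no correlation was estimated. The T cell list had a median log2 difference of 0.97, adjusted p = 2.03e-07 (camera), with 3 of 19 members higher and 16 not past the threshold (15 higher adjusted over the list alone). With an estimated correlation it and the other 13 lists called had an adjusted p of 0.913. The B cell list had 0.95, adjusted p = 0.000105, with 1 of 9 higher (8 adjusted over the list alone), which was Cd79b. The macrophage and monocyte list had 1.37, adjusted p = 6.60e-06, with 0 of 27 past the threshold by limma, also adjusted over the list alone, where 2769 of all genes had an unadjusted p under 0.05. Chemokine genes had 0.75, adjusted p = 3.51e-05, with 2 of 25 higher (11 adjusted over the list alone). MHC class I genes had 0.82, adjusted p = 0.00136 with 0 of 18 past the threshold by limma, also adjusted over the list alone. MHC class II genes had 1.16, adjusted p = 0.00198, with 0 of 12 past the threshold and 1 higher adjusted over the list alone. MRL/lpr 8 weeks replicate 3 had an MHC class I mean of 6.59, against 5.11 and 5.02 in its partners and 6.06 to 6.64 at 17 weeks. With 1 library left out the camera adjusted p of MHC class I ranged from 2.9e-11 to 0.0442. Proximal tubule genes leaned lower (-0.30, adjusted p = 2.28e-06), with 3 of 29 past the threshold (6 adjusted over the list alone). So did renin-angiotensin genes (-0.14, adjusted p = 0.00487), with 2 of 10 past it, among them Ren1 (3 adjusted over the list alone), and erythroid genes (-1.10, adjusted p = 0.00139), with 1 of 8 (5 adjusted over the list alone). These 9 of the 14 lists called kept their calls whichever library was left out. The interferon-stimulated list (0.61, adjusted p = 0.000543) was lost without MRL/lpr 8 weeks replicate 2 (0.0523). Over the fits with 1 library left out its adjusted p went down to 5.6e-12. Its mean in MRL/lpr 8 weeks replicate 3 was 3.735, against 2.488 and 2.378 in the partners and 3.355 to 3.726 at 17 weeks. The lists of complement (0.57, adjusted p = 0.0224), cytokine (0.66, adjusted p = 0.0313), nucleic acid sensing (0.47, adjusted p = 0.0290) and plasma cell genes (0.60, adjusted p = 0.0290) were also called. They were lost without 1 or more of MRL/lpr 8 weeks replicates 1 and 2 and MRL/lpr 17 weeks replicates 1, 2 and 3 (up to 0.0760, 0.0863, 0.114 and 0.116). In all, 213 of 12931 genes rose and 172 fell, 42 and 5 of them by at least 2-fold. The total of 385 became 2362 without C57BL/6 17 weeks replicate 2, with all 385 among them. That library is not in this comparison and acts through the shared spread. In that fit 17 of 19 T cell, 8 of 9 B cell, 23 of 27 macrophage and 13 of 25 chemokine genes were higher (17, 8, 26 and 18 adjusted over the list alone; adjusted p of up to 0.398 with an estimated correlation). The tubular injury list was then called (adjusted p = 0.0255, 8 of 18 higher and 1 lower), as was the inflammasome list (0.00293, 7 of 11 higher), with 8 and 9 higher and 1 lower in each adjusted over the list alone. With the correlation estimated these 2 had 0.712 and 0.351. The total became 231, 92 and 101 without MRL/lpr 17 weeks replicates 1, 2 and 3, 83, 122 and 119 without MRL/lpr 8 weeks replicates 1, 2 and 3, and 229 and 256 without C57BL/6 8 weeks replicates 2 and 3. The age comparisons share no library. In both strains 20 genes rose, against 1.3 expected of independent lists, and 25 fell, against 1.5, among them Pllp, Slc22a12 and Odc1. These lists too rest on the same fitted spread of each gene, so the expected numbers are only a rough guide.

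The interaction of strain and age asks which genes changed with age differently in the strains. Cyp27b1 was 1.5 ± 0.579 FPKM at 8 weeks and 10.1 ± 1.74 at 17 weeks in C57BL/6 kidneys, and 2.09 ± 0.108 and 1.40 ± 0.287 in MRL/lpr kidneys. The interaction was -2.53 ± 0.23 on the log2 scale (adjusted p = 0.00534) and held whichever library was left out. Chil1 (3.31 ± 0.39), the ubiquitin ligase gene Mylip (1.03 ± 0.12) and Hddc2 (0.74 ± 0.091) had positive interactions and Tent4a (-0.61 ± 0.067) a negative one, each with an adjusted p of 0.0141. Over its NM mRNAs alone Hddc2 had 0.96 (adjusted p = 0.342). Mylip was 15.8 ± 0.647 FPKM at 8 weeks and 29.97 ± 2.56 at 17 weeks in MRL/lpr, and 26.0 ± 1.86 and 23.3 ± 2.04 in C57BL/6 kidneys. Tent4a was 15.8 ± 0.490 and 10.1 ± 0.161 against 8.70 ± 0.0321 and 8.83 ± 0.259. The seminal vesicle gene Svs2 reached 1.93 ± 0.577 FPKM in the MRL/lpr 17 weeks libraries and was listed at 0 in the other 9 (adjusted p = 0.0220), and over NM mRNAs alone its adjusted p was 0.0738. Gm15056 (chromosome 8, 20900606 to 20902456), named after its values were seen, reached 10.7 ± 4.78 FPKM in those libraries, 0.207 ± 0.210 at 8 weeks and was listed at 0 in C57BL/6 (adjusted p = 0.0141). These were the 7 genes past the threshold, 5 positive and 2 negative, against 1331 with an unadjusted p under 0.05. Without C57BL/6 17 weeks replicate 2, 311 genes passed, all 7 among them, and without MRL/lpr 17 weeks replicate 3, 13 passed. Without C57BL/6 17 weeks replicate 1 or 3, C57BL/6 8 weeks replicate 1 or 3 or MRL/lpr 8 weeks replicate 2 or 3 the count was 1, and without C57BL/6 8 weeks replicate 2 it was 2. In those fits the lost calls had adjusted p values of up to 0.108. The list medians were 0.28, adjusted p = 0.00194 for collecting duct, 0.13, adjusted p = 0.00194 for oxidative phosphorylation, 0.17, adjusted p = 0.0134 for cholesterol synthesis and -0.22, adjusted p = 0.00546 for endothelial genes (camera). By limma 0 of their members passed the threshold, and 1 collecting duct gene did adjusted over the list alone. All 4 had an adjusted p of 0.997 with an estimated correlation. Without C57BL/6 17 weeks replicate 2 all 4 calls were lost, at medians of 0.27 for collecting duct (adjusted p = 0.0636), 0.02 for oxidative phosphorylation (0.523), 0.12 for cholesterol synthesis (0.705) and -0.10 for endothelial genes (0.0595). In that fit 9 other lists were called, 7 of them immune lists with positive medians and 2 of them lower, proximal tubule (-0.18, adjusted p = 3.28e-05) and hepatocyte genes (-0.16, 0.0412). The 9 had an adjusted p of 0.809 with an estimated correlation. By limma 0 of 43 interferon-stimulated and 0 of 18 MHC class I genes passed, also adjusted over the list alone, where 2785 of all genes had an unadjusted p under 0.05. Positive were 1 of 19 T cell, 1 of 9 B cell, 6 of 27 macrophage, 4 of 25 chemokine and 1 of 17 nucleic acid sensing genes (7, 5, 10, 7 and 4 adjusted over the list alone). Negative were 1 of 29 proximal tubule and 1 of 9 hepatocyte genes (5 and 1 adjusted over the list alone). The interferon-stimulated, MHC class I, T cell and B cell lists were also called without MRL/lpr 8 weeks replicate 3 (adjusted p of up to 0.0359), a fit in which no correlation was estimated. The T cell list was called without MRL/lpr 17 weeks replicate 2 as well. The B cell list was called without C57BL/6 8 weeks replicate 2, MRL/lpr 8 weeks replicate 1 or MRL/lpr 17 weeks replicate 3 too. Endoplasmic reticulum stress genes were called in 5 of the 12 fits with 1 library left out. The cholesterol and endothelial calls were also lost without MRL/lpr 17 weeks replicate 3.

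**Figure D4:**
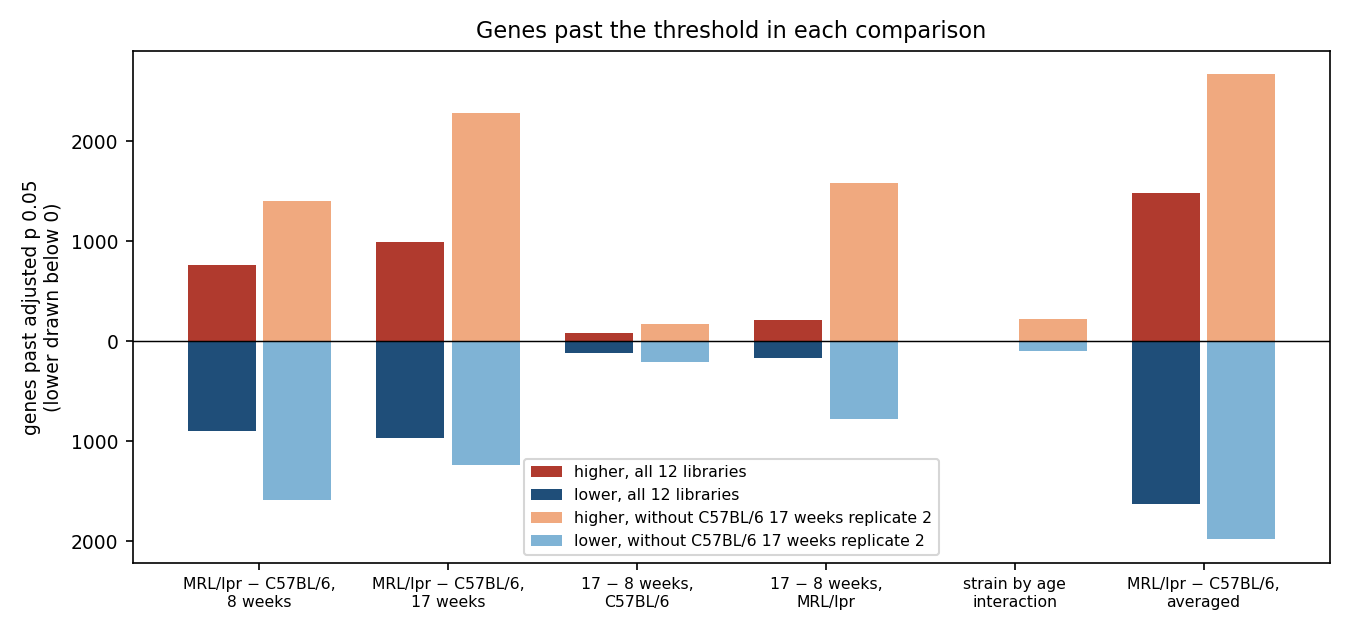
Number of genes higher and lower at an adjusted p of 0.05 in each comparison, with all 12 libraries and without C57BL/6 17 weeks replicate 2. Without that library the counts rise in every comparison, from 7 to 311 in the interaction.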

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

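The tests of C57BL/6 17 weeks replicate 2, of genes with near-identical copies and of the ratios between seminal vesicle genes were chosen only after the results were seen.

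Regroupings of the libraries were counted for each comparison. For each of the 4 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. At 8 weeks the real split of the strains gave 1660 genes and at 17 weeks 1955, and the age comparisons gave 193 in C57BL/6 and 385 in MRL/lpr, each in 1 of 10 splits. The highest of the other splits was 0 in all 4 by limma. At an unadjusted p under 0.05 the real splits had 3319, 3820, 2527 and 2769 genes. For the averaged strain difference 100 of 200 splits were taken, the real one among them. Only 1 of 100, the real one, gave 3108 genes or more, with 443 as the highest other. That is the smallest share that could be reached. It argues against a random division of these libraries, and it does not speak of separate animals, which the labels do not give. For the interaction 3 of 100 splits, again taken out of 200, gave at least the real 7 genes, a share under 0.05. These splits exchange ages within a strain and so also break up the age difference that the strains share. The share therefore cannot decide whether the 7 genes arose by chance. The highest other, 1305 genes, came from exchanging the ages of all MRL/lpr libraries. That points to a structure of the samples, a difference between 8 and 17 weeks shared by both strains. Age cannot be told apart there from time of day, which the labels do not give.

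Genes and lists whose change with age differed between the strains by the interaction test were as follows. Chil1 had 3.31 on the log2 scale, Mylip 1.03, Hddc2 0.74, Cyp27b1 -2.53 and Tent4a -0.61. Fitted values of Gm15056 (3.19) and Svs2 (1.53) depend on the pseudocount, since C57BL/6 is listed at 0 for both. So does that of Chil1, and so do the log2 differences of other genes with a group under 1 FPKM. List medians were 0.28 for collecting duct, 0.13 for nuclear oxidative phosphorylation, 0.17 for cholesterol synthesis and -0.22 for endothelial genes. All 4 list calls were lost with an estimated correlation (adjusted p = 0.997) and without C57BL/6 17 weeks replicate 2 (0.0636, 0.523, 0.705 and 0.0595), and by limma 0 of their members passed, against 1331 of all genes with an unadjusted p under 0.05.

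C57BL/6 17 weeks replicate 2 stood apart from its 2 partners, with macrophage, neutrophil and tubular injury genes higher. A mislabelled MRL/lpr library is argued against by 94 genes that separate the strains at 8 weeks, since on a scale from 0 (C57BL/6) to 1 (MRL/lpr) this library had a median of 0.003 with an upper quartile of 0.152, its partners 0 and -0.008, and the MRL/lpr libraries between 0.964 and 1.01. More medulla and less cortex is argued against by collecting duct genes, whose median was -0.172 relative to the partners (upper quartile 0.211) while proximal tubule genes were at -0.534. The 4 urothelial genes tested stood a median of 1.466 above the partners (quartiles 1.326 and 2.109), so another difference in the part sampled stays open. Their mean log2 level was 2.589, against 0.451 and 0.789 in the partners and 3.1 in C57BL/6 8 weeks replicate 2. Lymphoid tissue in the sample as the whole cause was tested by the tubular injury list, with a median of 1.908 over 18 members (lower quartile 1.243). That list shares Lcn2, Spp1, Lgals3, Ccl2 and Il34 with the immune lists, so its median alone cannot decide. Lymphoid tissue therefore stays open. Injury or inflammation of that kidney may remain as a cause, as may its handling, since immediate early and handling genes stood 1.061 above the partners (quartiles 0.747 and 1.415), and no biological explanation was tested, since the design names none for a single library.

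Several of the largest strain differences at 8 weeks lay in genes with near-identical copies, and the reference genome is that of C57BL/6J. The summed FPKM of the copies differed by 0.05 (log2) for Eno1 and Eno1b, 0.44 for Hmga1, 0.22 for Rnaset2 and 0.88 for Hba-a, with SE of 0.07, 0.03, 0.04 and 0.73, against 7.49 for Eno1b alone. For Eno1 at 8 weeks this is what reads of the same RNA divided differently between copies in the 2 strains would give. At 17 weeks the Eno1 sum differed by 0.16 (SE 0.04). The sums for Hmga1 and Rnaset2 were small beside 4.24 for Hmga1b and -6.67 for Rnaset2b alone, but differed by more than 2 SE. A division of reads therefore need not be the whole cause there. For Hba-a the SE is too wide to tell this apart from a difference in expression. The other copy moved the opposite way in these 4, by -1.01 for Eno1, -2.86 for Hmga1, 0.66 for Rnaset2a and 2.48 for Hba-a1. A division of reads is argued against as the whole cause for the Serpina1 genes at 8 weeks, whose sum differed by -3.16 (SE 0.24) and whose other copies together differed by -0.56. For Serpina1 at 17 weeks (-1.26, SE 0.42) and for Gsta1 and Gsta2 at 8 weeks (-1.41, SE 0.30), the sums lie within 2 SE of the limit of 1. They cannot decide how much of these differences comes from a division of reads and how much from expression. Strain differences in copy number, in sequence or in the expression of single copies stay open, untested.

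Seminal vesicle secretory genes were found in the 3 MRL/lpr 17 weeks libraries, with Svs4 at 3.64, 3.39 and 1.28 FPKM and Svs5 at 3.37, 3.72 and 1.42. Of 8 genes of the same list not looked at before, 5 (Svs1, Svs3b, Pate4, Spinkl and Sva) were above 0 FPKM in all 3 and below 0.1 in the other 9 libraries, so seminal vesicle RNA in these libraries is a candidate source. Spink1, at 397 to 962 FPKM in all 12 libraries, is expressed by the kidney, and Sbp (0.29 to 0.86 in all MRL/lpr libraries) and Tgm4 (0.02 to 0.19) did not follow the pattern. Expression by MRL/lpr kidney cells at 17 weeks cannot be told apart from it: a gene's share of the group differed by up to 6.47 times between the 3 libraries, above the 3 written for separately regulated genes, but that gene, Pate4, is near the floor, and all 3 libraries belong to 1 group. In all 12 libraries the Y-linked genes Ddx3y and Kdm5d stayed at or below 0.02 FPKM, Uty at or below 0.24 and Eif2s3y at or below 0.58. These values gave no sign of male kidneys, so they do not back seminal vesicle RNA from the same mice, and the labels give no sex. Age, strain and any difference in sampling stay open.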

How the results depend on the processing

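Chosen only after the data were seen were the 3 scalings of FPKM, library weights, NM mRNAs only, and the estimated correlation and fry without C57BL/6 17 weeks replicate 2. No count of genes changed sides, and of the values of single genes 2911 kept direction and side of the threshold, 463 lost the call and 0 reversed, while 5 gained a call and 5 moved, all of Fas. Counts at 8 and 17 weeks, in C57BL/6 with age, in MRL/lpr with age and on average became 945, 1069, 55, 131 and 1966 with NM mRNAs only, where fewer records enter each sum; 328, 350, 21, 47 and 357 with at least 2-fold as well, which keeps a subset; and 3456, 5144, 2507, 2384 and 5644 with library weights, under which the interaction gave 892 and C57BL/6 17 weeks replicate 2 had a weight of 0.089. With only the groups compared the first 4 became 2538, 846, 11 and 1096, by fits of 6 libraries. The replicate number as a term, which does not pair samples, gave 57 and 154 for the age comparisons and 1 for the interaction, median-of-ratios scaling 117 for C57BL/6 with age, no filter 12 and a pseudocount of 0.1 4 for the interaction; the cause was not tested. Other scalings, filters and pseudocounts stayed within 1.5 times.

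With 1 library left out, which leaves a group of 2, counts ranged from 1078 to 2986 at 8 weeks, 1279 to 3521 at 17 weeks, 15 to 375 in C57BL/6 with age, 83 to 2362 in MRL/lpr with age, 1 to 311 for the interaction and 2442 to 4651 on average. Lists ranged from 7 to 14, 7 to 15, 5 to 29, 11 to 17, 3 to 10 and 10 to 14. Each highest gene count came without C57BL/6 17 weeks replicate 2. An estimated correlation left 0 lists by camera in all 6 comparisons, with and without that library. Fry called 4 lists at 8 weeks, 3 at 17 weeks, 9 on average and 0 for both age comparisons and the interaction. Without that library it called 8, 20 and 24, then 13 for MRL/lpr with age and 0 for C57BL/6 with age and the interaction. At an unadjusted p under 0.05, 2527 genes passed for C57BL/6 with age, 2769 for MRL/lpr with age and 1331 for the interaction with all 12 libraries, and 2702, 4362 and 2785 without that library. Alternatives that need counts (edgeR factors, DESeq2 and voom) were not run, nor was leaving out immunoglobulin, T cell receptor and mitochondrial genes, since no such gene has a value here. The read depth is known only as an estimate, so what it limits is open.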

Other observations

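No test in this part was run beyond the comparisons above, and Nr1d1, C2, C3, Alb, Apoa1, Ahsg, Cd8b1 and Jchain were singled out after their values were seen. The labels give no time of day. Of the clock genes, Cry2 rose with age in both strains (log2 0.75 ± 0.077 in C57BL/6 and 0.82 ± 0.077 in MRL/lpr), with the limit of its NM mRNAs given above. The repressor Nr1d1 had 58.3 ± 1.70 FPKM at 8 weeks and 32.0 ± 8.27 at 17 weeks in C57BL/6, and 50.5 ± 4.04 and 28.8 ± 7.33 in MRL/lpr kidneys, lower in 6 of 6 older libraries than in any younger one. Per3 had 8.62 ± 0.793 and 10.8 ± 0.355 FPKM in C57BL/6, and 10.3 ± 1.84 and 14.8 ± 0.227 in MRL/lpr. By limma 1 of 16 clock genes was higher with age in C57BL/6 and 3 in MRL/lpr kidneys (2 and 4 adjusted over the list alone, with 1 and 2 lower), and the list was not called by camera (adjusted p = 0.620 and 0.727).

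Complement genes went both ways between the strains at 8 weeks, with 2 of 20 higher and 3 lower in MRL/lpr kidneys (3 and 3 adjusted over the list alone; camera adjusted p = 0.846). Those higher were C2 (0.48) and Cfb (0.47), and among those lower were Cd55 (-0.76) and Cd59a (-0.55). C3 stood at 234 FPKM in C57BL/6 17 weeks replicate 2, between 9.42 and 13.0 in the other C57BL/6 libraries, between 16.0 and 25.4 in MRL/lpr at 8 weeks and between 44.0 and 79.2 at 17 weeks.

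C57BL/6 17 weeks replicate 3 held 60.4 FPKM of Alb, 11.8 of Apoa1 and 9.81 of Ahsg, all abundant in liver, against at most 11.8, 1.39 and 0.09 in the other 11 libraries. Cd8a lay between 12.4 and 15.9 FPKM in the 6 MRL/lpr libraries, while Cd8b1, which encodes the other chain of the receptor, stayed at or below 1.39. Jchain, which joins immunoglobulin chains in plasma cells, was at 195, 241 and 11.2 FPKM in the MRL/lpr 17 weeks libraries and at 32.0, 98.2 and 27.1 in those of C57BL/6, and did not exceed 16.1 in the 6 libraries of 8 weeks.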
